A study of Nicotiana benthamiana with 12 samples.

How the data were processed

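RNA from whole seedlings of Nicotiana benthamiana, a relative of tobacco used widely as a laboratory plant, was sequenced in 12 libraries. Per the labels, seedlings of the LAB strain were moved from plates into liquid medium 10 days after germination, grown there for 10 days, and then given fresh medium with 10 µM abscisic acid (ABA, the plant hormone of the drought response and of seed dormancy) or with 0.1% of its solvent DMSO as mock, and were collected after 3 h. Both treatments were given to wild type (WT) and to a line labelled pent1, whose altered gene is not given in the sources used here. Each of the 4 groups held 3 libraries, which the design text calls independent biological replicates.

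The values used were whole-number read counts per gene as deposited by the authors, without normalization. Per the labels' protocols, libraries were made with a strand-specific mRNA kit of the DNBSEQ platform. Per the submitters' processing notes, FastQC, cutadapt, STAR and DESeq2 were used, with no versions or settings. The read counter, the genome build, the annotation, the use of strand and the treatment of reads that match several places are not given in the sources used here. N. benthamiana is an allotetraploid with many pairs of near-identical gene copies, so a count for 1 copy may include reads of its partner. Both genotypes had their counts in separate tables with the same 45796 gene IDs, of which 4139 had no count in any library. Columns were assigned to samples by the sample descriptions in the labels, and no ID stood for anything other than a gene.

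The total counts per library were 18199288 to 18758918 in WT and 19371555 to 19678708 in pent1. Pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 2.03 to 16.5 over the 12 pairs (genes with at least 20 counts in the pair), so each library was kept as a separate replicate. Counting intervals and floors printed for single genes are at 95% and cover counting error only. The floor was 3 counts over the 3 libraries of a group. Folds given as "at least" set a group without counts to this floor and leave out the counting error of the other group.

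The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 with robust dispersion, TMM normalization and the default filterByExpr filter (a count minimum of 10), with Benjamini-Hochberg adjustment and a threshold of 0.05. ABA was compared with mock within each genotype on its own 6 libraries. The difference of the ABA response between the genotypes, and pent1 against WT under each treatment, were tested on all 12 libraries with 4 group means. Positive values stand for higher with ABA, or for higher in pent1. Standard errors of log2 fold changes are those implied by the F statistic. Because each genotype has a table of its own and the labels name no batch, genotype cannot be told apart from any difference in growth, sequencing or counting between the tables. A shift that acts alike on mock and ABA cancels in the difference of responses, and any other does not.

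Overlap of the responses was tested with Fisher's exact test among genes tested in both genotypes. The size of the pent1 response relative to WT was measured by calling genes on 2 WT replicates, taking the WT fold change from the replicate left out, and averaging over the 3 choices. This removes the bias of choosing and measuring on the same WT libraries. It leaves the bias of choosing genes by their WT response alone, which favours a ratio below 1. Levels of gene sets chosen on libraries that also enter a genotype comparison were measured again in the same way in libraries left out of the choice, a check added after the results were seen. Plant gene lists drawn up before the data were examined could not be used, since no table used here pairs the IDs with names or products. Genes are therefore named by ID, under a rule also set in advance: in each of the ABA comparisons, the difference of responses and the mock comparison of genotypes, the 2 highest and 2 lowest by log2 fold change with an adjusted p under 0.05, an average log2 CPM of at least 1 and, outside the difference of responses, no overlap between the groups' libraries. CPM are counts relative to the TMM-scaled library size, in the usual unit.

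The tests were tried on simulated data in which 50 genes were changed at each of several fold changes. At 2-fold, 86% were recovered in the WT comparison, 80% in pent1, 60% for the difference of responses and 82% for the mock comparison of genotypes. At 1.5-fold the shares were 76%, 26%, 18% and 54%. In the same order of comparisons, 29, 26, 19 and 11 unchanged genes were also called. In each comparison these were more than a 0.05 share of the calls, so the threshold was not fully held in these simulations. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, a 2-fold minimum, all 12 libraries in one fit, and each library left out in turn. Figures were drawn with matplotlib 3.10.9.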

Results

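Transcript levels were measured by RNA sequencing of whole N. benthamiana seedlings in 4 groups of 3 libraries, from WT and pent1 plants given mock or 10 µM ABA for 3 h. Libraries held 18199288 to 19678708 counts, and 37692 to 38512 genes had at least 1 count. The gene with the most counts took 1.33% to 1.85% of a library and the top 10 genes took 4.41% to 5.86%. WT libraries were smaller than pent1 libraries without overlap, and held counts in more genes (38308 to 38512 against 37692 to 37937). In a principal component analysis the first component held 39.5% of the variance and the next held 36.0%, and together they separated all 4 groups. Replicates lay closer together in WT, with a biological coefficient of variation of 0.0630 against 0.129 in pent1. The pent1 ABA library of replicate 3 lay farthest from its group, at a root mean square log2 distance of 0.40.

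**Figure D1:**
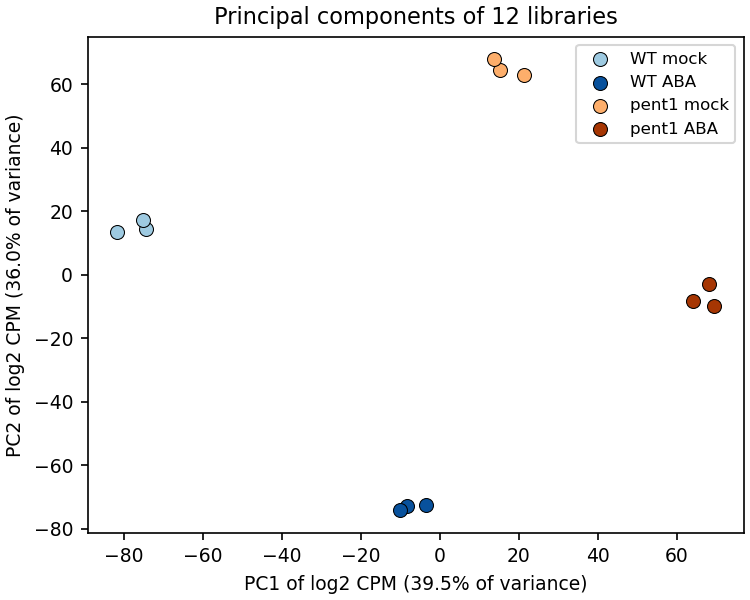
Principal components of log2 CPM, with the first component (39.5% of variance) on the x axis, the next (36.0%) on the y axis and 1 point per library, coloured by group. Each of the 4 groups forms a separate cluster of 3 libraries.

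The comparison of ABA with mock in WT asked which transcripts the hormone changed within 3 h. ABA changed 11953 of 33170 tested genes (36.0%), with 6156 higher and 5797 lower. DESeq2 called fewer, 8960 genes with 5159 higher and 3801 lower, and kept 73.7% of these calls. Most changes were small, with a median log2 fold change of 0.57 among the higher genes and -0.42 among the lower, but large changes were mostly increases. At least 2-fold, 1641 genes were higher and 746 lower, and at least 4-fold, 542 were higher and 130 lower. From summed group counts, with groups of 3 or fewer counts set to the floor, 133 genes were at least 16-fold higher and 13 were at least 16-fold lower.

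The genes at least 2-fold higher in WT took 1.30% ± 0.0714 of all counts in WT mock and 4.18% ± 0.20 in WT ABA (SD, n = 3). The genes at least 2-fold lower fell from 1.10% ± 0.0551 to 0.416% ± 0.018 (SD, n = 3). These sets were chosen on the same libraries, and an exact two-sided permutation test of 3 against 3 libraries gave p = 0.1 for each, the smallest it can give. The split of directions depended on scaling: upper-quartile factors gave 5113 higher and 8042 lower genes, and library-size scaling alone gave 5879 and 6023.

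Of the genes highest by fitted fold change under the naming rule in WT, NbL02g23280 had no count in the 3 mock libraries and stood at 26.4 ± 3.11 CPM with ABA (SD, n = 3), at least 489-fold higher. NbL01g21980 likewise had no mock count and stood at 12.5 ± 1.18 CPM with ABA, at least 232-fold higher. Their adjusted p-values were 6.61e-15 and 8.64e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. NbL08g02530 fell from 4.09 ± 0.906 to 0.109 ± 0.0525 CPM, a log2 fold change of -5.14 (SE 0.36, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.94e-10). NbL10g07970 fell from 7.04 ± 0.455 to 0.253 ± 0.121 CPM, a log2 fold change of -4.75 (SE 0.25, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.97e-12).

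The same comparison in pent1 found 3678 of 33197 tested genes changed (11.1%), with 2402 higher and 1276 lower. The changes called were larger than those called in WT, with median log2 fold changes of 0.89 and -0.74. At least 2-fold, 1014 genes were higher and 380 lower. From summed group counts, with groups of 3 or fewer counts set to the floor, 67 were at least 16-fold higher and 6 at least 16-fold lower. Counts in the genes that were at least 2-fold higher in WT rose from 1.99% ± 0.0686 in pent1 mock to 4.11% ± 0.195 in pent1 ABA (SD, n = 3, exact permutation p = 0.1, the smallest possible). The number of calls varied with the libraries fitted. It was 6206 with all 12 libraries in one fit, where WT had 8324, and 6011 without pent1 ABA replicate 3, 2402 without pent1 ABA replicate 2 and 2345 without pent1 mock replicate 1. Library-size scaling alone gave 1912 higher and 2039 lower genes.

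NbL05g00710 had no count in pent1 mock and stood at 30.4 ± 9.34 CPM with ABA (SD, n = 3), at least 613-fold higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.39e-05). In WT it had 2 counts in mock and 2889 with ABA, a ratio of 1467 with a 95% counting interval of 405.7 to 12120. NbL02g23280 had no count in pent1 mock either and reached 6.51 ± 4.55 CPM, at least 132-fold higher. Its 3 ABA libraries differed widely, and the edgeR quasi-likelihood call (Benjamini-Hochberg adjusted p = 0.043) was lost without a filter on low counts (adjusted p = 0.129), with library-size scaling alone (0.0665), and without pent1 mock replicate 1 (0.0872), pent1 ABA replicate 2 (0.128) or pent1 ABA replicate 3 (0.0541). NbL08g13010 fell from 7.41 ± 1.43 to 0.458 ± 0.221 CPM, a log2 fold change of -4.01 (SE 0.29, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.26e-06). NbL10g07970, among the lowest in WT as well, fell from 9.47 ± 1.46 to 0.594 ± 0.155 CPM, a log2 fold change of -3.98 (SE 0.23, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.86e-07).

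Among 32536 genes tested in both genotypes, the responses overlapped. Of the pent1 calls, 81.3% were also called in WT in the same direction. A total of 2081 genes were higher in both, where independent lists would share 442.9, and 870 were lower in both, against 219.9. Opposite calls were made for 29 genes, a number that was 348 without pent1 ABA replicate 3, 6 without pent1 ABA replicate 2, 14 without pent1 ABA replicate 1, and 8 without either pent1 mock replicate 1 or 3. The odds ratio of being called in both was 10.5 (95% interval 9.58 to 11.5, Fisher's exact test). Across genes, which are not independent replicates, fold changes had a Pearson correlation of 0.778 and a Spearman correlation of 0.437. Without a filter on low counts the Pearson correlation was 0.494.

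Among genes chosen by their response in WT, the response of pent1 was smaller in size. Choosing genes by WT alone itself favours a smaller value in pent1, and the ratio was not measured for genes chosen in pent1. For genes called higher in pent1, the median pent1 minus WT log2 difference was 0.17 under mock and 0.11 under ABA. For genes called lower in pent1 it was 0.11 and 0.03. A smaller pent1 response was thus not clear in that choice, which was made on the same pent1 libraries and favours a larger one. With WT fold changes from replicates not used to choose the genes, the mean change in pent1 was 0.592 ± 0.0639 of that in WT (SD over 3 pent1 ABA libraries, which gave 0.540, 0.572 and 0.663). The ratio was 0.641 for genes higher in WT and 0.501 for genes lower in WT, and the slope of pent1 on WT fold changes was 0.653. The mean log2 change in the WT direction was 0.75 ± 0.02 in WT and 0.44 ± 0.05 in pent1 (SD, n = 3, exact two-sided permutation p = 0.1, the smallest possible). Each WT value used 1 ABA and 1 mock library, whereas the 3 pent1 values share the mean of the 3 pent1 mock libraries. Both pent1 SDs thus leave out the spread of pent1 mock, and the permutation compares values built in unlike ways.

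**Figure D2:**
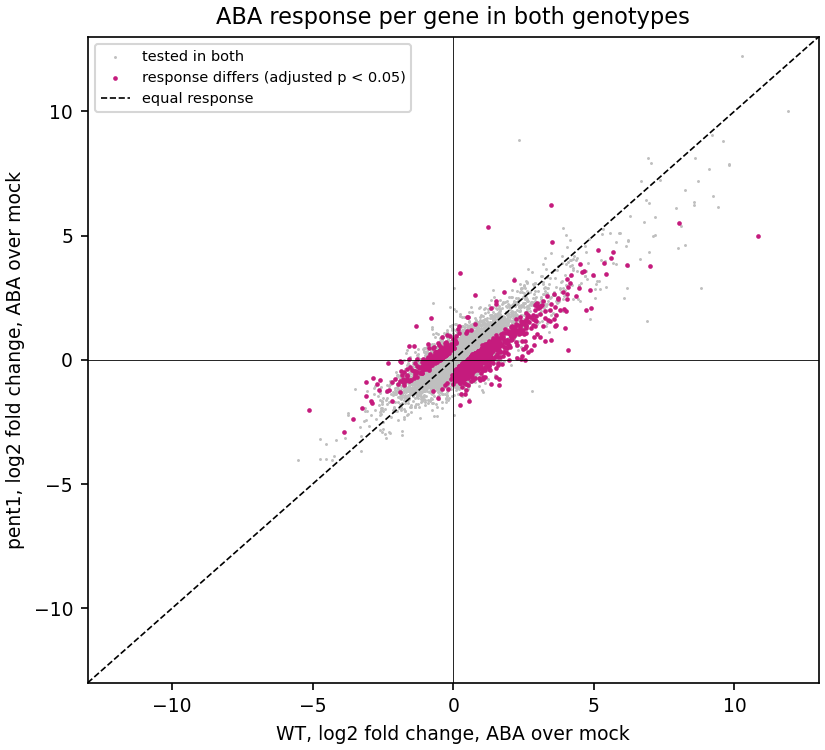
Log2 fold change of ABA over mock in WT (x axis) and pent1 (y axis), with 1 point per gene for the 32536 genes tested in both genotypes, genes with a different response (adjusted p under 0.05) in magenta and a dashed line for equal response. Of the magenta genes with a call in WT, 1012 lie on the side of the line toward or past no response in pent1 and 19 on the other.

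A direct test of the difference between the genotypes' responses called 1145 of 34026 genes, 408 with a positive difference and 737 with a negative one. Of these genes, 1138 were tested for ABA in both genotypes and 1031 of those had a call in WT, of which 1012 had a weaker or opposite response in pent1 and 19 a stronger one. The largest class, 668 genes, was higher with ABA in WT (median log2 fold change 0.99) and had a median of 0.13 in pent1. A smaller class of 344 genes was lower with ABA in WT (-0.49) and had a median of 0.13 in pent1. The WT libraries serve in both the choice and the difference, which favours weaker over stronger responses.

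The number of genes called was unstable. Leaving out 1 library moved it by more than 1.5 times for each of the 12 libraries: it was 355 to 516 without any of the 6 WT libraries, 744, 1761 and 578 without pent1 mock replicates 1, 2 and 3, and 734, 502 and 5334 without pent1 ABA replicates 1, 2 and 3. Weaker responses outnumbered stronger ones in each of these fits, with 332 against 3 in the smallest and 3435 against 124 in the largest. DESeq2 called 1903 genes. Scaling moved the directions, with 567 positive and 614 negative under upper-quartile factors and 196 and 1211 under library-size scaling alone.

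Levels in mock and ABA were compared for the classes with weaker responses. Of the 668 genes, 494 were higher in pent1 than in WT under mock and 15 were lower, with a median log2 difference of 0.75. Under ABA, 254 were lower in pent1 and 161 higher, with a median difference of -0.16. Relative to WT mock, the median log2 level of the class was 1.00 ± 0.03 in WT ABA, 0.75 ± 0.03 in pent1 mock and 1.07 ± 0.02 in pent1 ABA (SD, n = 3), so under ABA the median of levels and the median of differences had opposite signs. Of the 344 genes, 227 were lower in pent1 under mock and 7 higher, and under ABA 154 were higher and 15 lower. A choice by the difference of responses itself favours these directions. In libraries left out of the choice, the raised class again stood higher in pent1 mock, by medians of 1.03 (212 genes), 1.91 (20 genes) and 0.50 (1037 genes) without replicates 1, 2 and 3, whereas the medians under ABA differed in sign (0.39, -0.21 and 0.02). The lowered class stood lower in pent1 mock, by medians of -0.10 (16 genes), -0.25 (1 gene) and -0.37 (596 genes), and its medians under ABA were 0.73, 0.07 and -0.10, so its direction under ABA was not kept in the largest set.

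**Figure D3:**
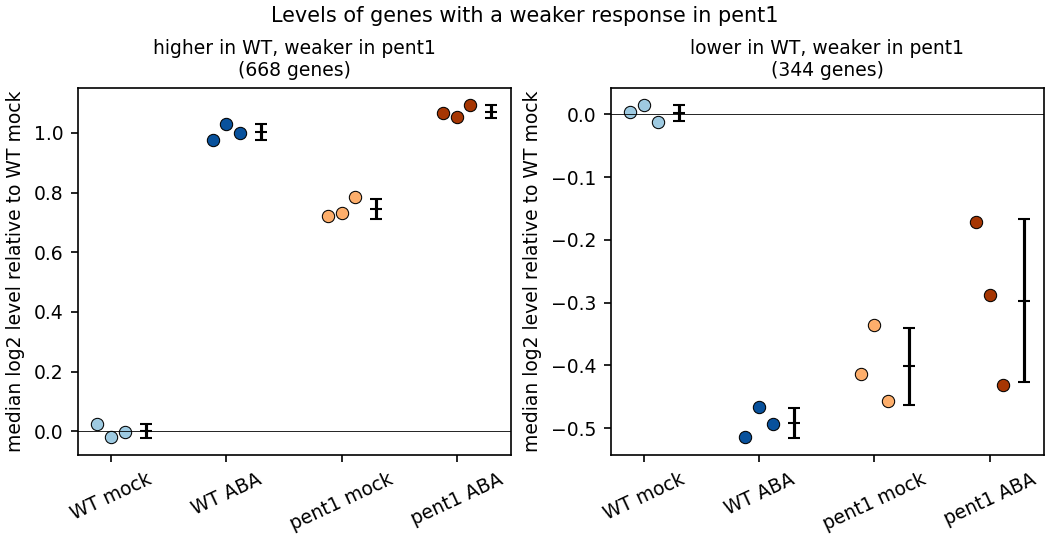
Median log2 level relative to WT mock for the 668 genes higher with ABA in WT and weaker in pent1 (left) and the 344 genes lower with ABA in WT and weaker in pent1 (right), with 1 point per library and bars for mean and SD of each group (n = 3). In these libraries, on which the classes were chosen, pent1 mock stands away from WT mock in the direction ABA moved the class in WT, at 0.75 and -0.40.

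NbL10g24460, named for a positive difference, rose from 12.5 ± 2.01 to 29.5 ± 0.911 CPM in WT and from 0.309 ± 0.139 to 13.1 ± 0.366 CPM in pent1 (SD, n = 3), ratios of 2.36 and 41.7. The log2 difference was 4.12 (SE 0.26, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.64e-07). NbL15g14570 rose from 0.503 ± 0.165 to 64.6 ± 2.96 CPM in WT and from 2.81 ± 0.798 to 39.1 ± 10.4 CPM in pent1, ratios of 128.4 and 13.9. Its log2 difference was -3.19 (SE 0.40, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000974). NbL01g21980, at 0 counts in WT mock, had 17 counts in pent1 mock and 520 in pent1 ABA, a ratio of 32.5 (95% counting interval 20.1 to 56.2) against at least 232-fold in WT. Its edgeR quasi-likelihood call (Benjamini-Hochberg adjusted p = 0.0269) was lost without WT mock replicate 1 (0.0664), 2 (0.0695) or 3 (0.072) or WT ABA replicate 2 (0.0534). NbL08g02530 fell in pent1 from 5.96 ± 0.654 to 1.47 ± 0.958 CPM, less steeply than in WT, with a log2 difference of 3.12 (SE 0.71). Its edgeR quasi-likelihood call (Benjamini-Hochberg adjusted p = 0.0286) was lost with limma-voom (0.062) and without WT mock replicate 2 (0.0626) or 3 (0.0602), WT ABA replicate 1 (0.105), 2 (0.0726) or 3 (0.0813), pent1 mock replicate 1 (0.0502) or 3 (0.0503), or pent1 ABA replicate 1 (0.0522).

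**Figure D4:**
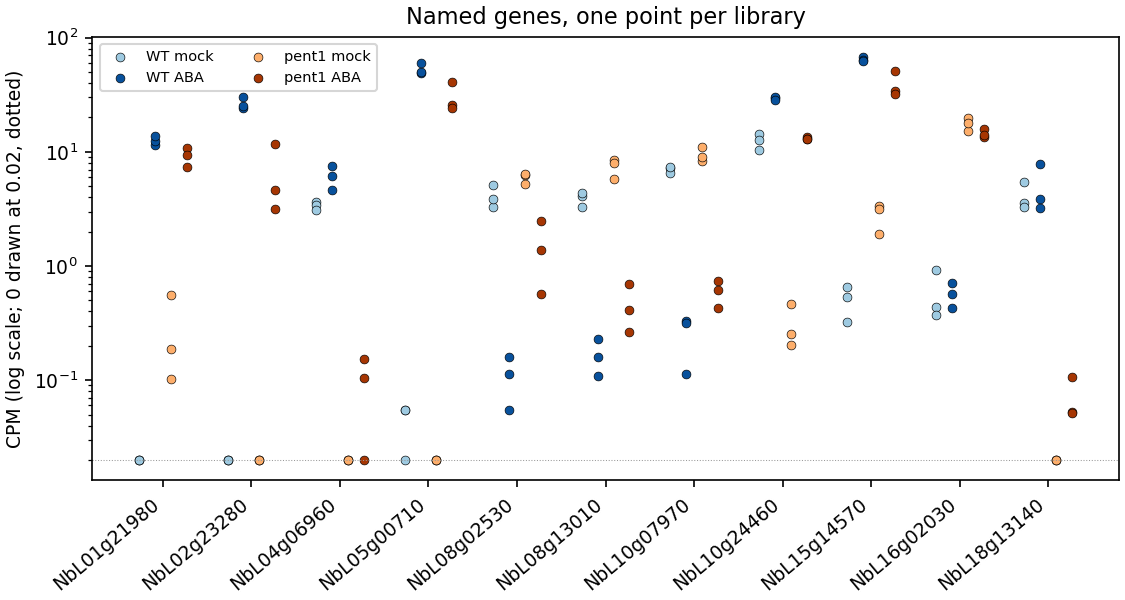
CPM on a log scale for the 11 named genes, with 1 point per library coloured by group and values of 0 drawn at 0.02 (dotted line). NbL10g24460 is low in pent1 mock alone, and NbL04g06960 and NbL18g13140 are at 0 in all 3 pent1 mock libraries.

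Under mock, pent1 and WT differed in 11158 of 34026 genes (32.8%), with 5913 higher and 5245 lower in pent1. The majority turned with upper-quartile factors (5186 higher, 6180 lower), without a filter on low counts (5464, 5939), and without WT mock replicate 2 (4243, 4315) or pent1 mock replicate 2 (4859, 4930). Genes that ABA raised in WT tended to be higher in pent1 without ABA: of 6047, 2353 were higher and 380 lower, with a median log2 difference of 0.26. Genes that ABA lowered in WT tended to be lower: of 5737, 2184 were lower and 500 higher, with a median of -0.24. Both medians kept their sign under each scaling, at 0.24 to 0.30 and -0.26 to -0.20, and were 0.21 and -0.26 in WT libraries left out of the choice. Genes at least 2-fold higher with ABA in WT took 1.99% ± 0.0686 of counts in pent1 mock against 1.30% ± 0.0714 in WT mock (SD, n = 3, exact permutation p = 0.1, the smallest possible). Both comparisons use the WT mock libraries. Fold changes correlated across genes at 0.249, against 0.153 ± 0.00775 in 20 simulations that kept the WT ABA response and had no genotype effect. These correlations are not on one scale, since the simulated genotype differences held noise alone, and their smaller variance raises the correlation. The covariance does not have this limit, and was 0.096 against 0.0202. The simulations used the spread of the 12-library fit, a biological coefficient of variation of 0.102 against 0.0630 in WT. With separate WT mock libraries for each comparison the correlation was 0.176 to 0.229.

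The largest differences under mock were decreases. From summed group counts, with groups of 3 or fewer counts set to the floor, 136 genes were at least 16-fold lower in pent1 and 12 at least 16-fold higher. NbL18g13140 stood at 4.11 ± 1.17 CPM in WT mock and had no count in pent1 mock, at least 82.8-fold lower, and NbL04g06960 stood at 3.40 ± 0.259 CPM and had none, at least 68.6-fold lower (SD, n = 3). Their adjusted p-values were 4.00e-06 and 4.08e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Under ABA they had 4 and 5 counts in pent1. NbL16g02030 was higher in pent1 mock, at 17.6 ± 2.21 CPM against 0.577 ± 0.304, a log2 fold change of 4.92 (SE 0.21, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.70e-11). NbL01g21980, with 17 counts against 0, was at least 5.20-fold higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00536).

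Under ABA the genotypes differed in 10651 genes (31.3%), with 5669 higher and 4982 lower in pent1. The majority turned with RLE factors (5076 higher, 5475 lower), library-size scaling alone (4786, 5222), DESeq2 (4429, 5231), no filter on low counts (5328, 5437), a 2-fold minimum (914, 1105) and without pent1 mock replicate 1 (4841, 5699). Of 6047 ABA-raised genes, 1166 were higher and 1284 lower, with a median of -0.01. Of 5737 ABA-lowered genes, 1284 were higher and 716 lower, with a median of 0.10. Both sets were chosen on the same WT ABA libraries, and in WT libraries left out of the choice the medians were -0.02 and 0.04, against 0.01 for all tested genes. The share of counts in genes at least 2-fold higher with ABA in WT was 4.18% ± 0.20 in WT ABA and 4.11% ± 0.195 in pent1 ABA (SD, n = 3, exact permutation p = 0.7). In both genotype comparisons, genotype coincided with the table of counts.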

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

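The tests of spread between libraries and of lower sensitivity in this part were chosen after the result was seen, unlike the tests of mixed RNA and of other splits.

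A difference between the genotypes' ABA responses was called for 1145 genes, and among the genes named by rule the log2 differences were 4.12 for NbL10g24460, 3.12 for NbL08g02530, -5.91 for NbL01g21980 and -3.19 for NbL15g14570. The value for NbL01g21980 is set partly by the prior count, since WT mock held no count of it.

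The pattern weighed is the smaller ABA response in pent1. Greater spread among pent1 libraries lowers the number of calls but leaves mean changes at the WT size, whereas the mean change was 0.592 ± 0.0639 of that in WT (SD over 3 pent1 ABA libraries). This SD leaves out the spread of pent1 mock. Without pent1 mock replicates 1, 2 and 3 in turn, the slope of pent1 on WT was 0.651, 0.662 and 0.643. The genes were chosen by their WT response, which itself favours a ratio below 1. Among genes called in pent1 a smaller response was not clear, though that choice favours a larger one. ABA-treated RNA in the pent1 mock libraries would need a share of 24.5% to give their excess of counts in induced genes, but 37 genes near silence in WT mock and on in WT ABA stood in pent1 mock at a median of 1.61% of their pent1 ABA level (95% bootstrap interval 0.911 to 3.40), with 1 gene at or above the share needed. Of 100 splits drawn with genotypes regrouped within treatments, 4 gave as many genes as the real one, itself included, a share under 0.05. The highest other gave 3255 genes. The 3 larger splits kept WT mock together and mostly exchanged the genotypes under ABA, so they measure the genotype difference, a structure of the samples. The other splits also mixed the genotypes within groups, which widens the spread, and most gave no calls. The share thus depends on which splits were drawn and cannot decide whether chance gave the count. Lower sensitivity to ABA from equal levels under mock is argued against by WT libraries left out of the choice. There, genes raised in WT were higher in pent1 mock (median log2 difference 0.21, 0.19 to 0.22 over the 3 choices) and differed less under ABA (-0.02, -0.0544 to -0.00463). Genes lowered in WT were lower in pent1 mock (-0.26, -0.262 to -0.254) and differed less under ABA (0.04, 0.0386 to 0.0491). A shift of these genes alike in mock and ABA, together with lower sensitivity, would give the same values, so they cannot exclude lower sensitivity as the cause of the smaller response. A different state of pent1 before treatment may account for the mock differences. Lower sensitivity stays open beside it, as among genes at least 2-fold lower in WT (-0.22 under mock, 0.25 under ABA). A difference in growth or treatment between the experiments behind the tables cannot be told apart from genotype.

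For the other comparisons, the 10 splits of 3 against 3 libraries are too few for a share under 0.05, so other splits of the samples gave only these counts: in 1 split of 10, the real one, 11953 genes were called for ABA in WT, 3678 for ABA in pent1, 11158 for genotype under mock and 10651 for genotype under ABA, and the highest of the others was 0 in each. Every other split mixed the treatments or the genotypes within its groups, which widens the spread and makes calls unlikely. The counts of 0 thus decide nothing about chance.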

How the results depend on the processing

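All alternatives were chosen before the data were examined except library-size scaling alone and the ratio of mean changes, which were added afterwards. No named gene changed direction under any alternative. The larger of the higher and lower counts of calls turned for ABA in WT with upper-quartile factors (5113 higher, 8042 lower) and library-size scaling alone (5879, 6023), and for ABA in pent1 with library-size scaling alone (1912, 2039). It also turned for genotype under mock in 4 fits and for genotype under ABA in 6, listed with those comparisons, so neither genotype comparison has a stable majority direction. A 2-fold minimum lowered the counts by construction, to 2387 (ABA in WT), 1394 (ABA in pent1), 319 (difference of responses), 2486 (genotype under mock), 2019 (genotype under ABA) and 1084 (overlap). The pent1 count was 6206 with all 12 libraries in one fit, and the difference of responses gave 1903 genes with DESeq2. The cause was not tested for either. A fit of all 12 libraries shares its estimate of spread between the genotypes. Its biological coefficient of variation was 0.102, against 0.129 in pent1 alone and 0.0630 in WT alone. The difference of responses and both genotype comparisons rest on this shared spread. With 1 library left out, the counts ranged from 10012 to 11251 (ABA in WT), 2345 to 6011 (ABA in pent1), 355 to 5334 (difference of responses), 8558 to 12682 (genotype under mock), 7567 to 11785 (genotype under ABA) and 2072 to 3387 (overlap). With 1 pent1 library left out, the slope ranged from 0.643 to 0.662. Over the 3 choices of the WT replicate held out, it ranged from 0.640 to 0.661. Without pent1 ABA replicate 3, 1144 of the 1145 genes with a different response were still called. The correlation of responses was 0.494 without a filter and 0.715 without pent1 ABA replicate 3. Of 280 values of named genes under alternatives, 261 kept their call and 19 lost it. The replicate block gave 12024, 4087, 1494, 11031 and 10546 genes for the 5 comparisons and 3076 for the overlap, with 84 opposite calls in place of 29, and among the named genes it ended the call of NbL01g21980 for the difference of responses (adjusted p = 0.0659 by edgeR with Benjamini-Hochberg adjustment, 0.00184 to 0.072 over all its alternatives) and no other. Same-numbered libraries did not deviate together (correlations of -0.0446 to 0.0727), and 1 of 3 numbers in each genotype correlated best with its own, so the numbers were not taken as pairs. Depth limited genes near 0 counts. Their ratios are given as bounds over a group without counts, or with a counting interval, and the fitted difference of NbL01g21980 is set partly by the prior count. Set tests of the gene lists were not run, since no table used here pairs IDs with names.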

Other observations

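In this part, 3 tests were chosen only after the result was seen. They are those of a table difference, of read depth, and of whether most genes at least 16-fold lower in pent1 mock have a neighbour in their set. ABA switched some genes on from near silence. In WT, 38 genes had at most 3 counts over the 3 mock libraries and at least 1 CPM in every ABA library, and 1 gene went the other way. In pent1 the numbers were 16 and 0, with 14 of the 16 among the 38. Of the 38, 29 also had at least 1 CPM in every pent1 ABA library, and 19 had 4 or more counts in pent1 mock.

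As a ratio, the pent1 response came closer to that of WT where the WT response was larger. For genes higher with ABA, the ratio of mean changes was 0.357 below a WT log2 fold change of 0.5 (1816 genes), 0.586 from 0.5 to 1 (1735), 0.685 from 1 to 2 (1103), 0.720 from 2 to 4 (419) and 0.772 from 4 (143). For genes lower with ABA it was 0.22 (2231), 0.544 (1314), 0.651 (601) and 0.689 (134) over the same classes, and 0.710 in the last, which held 17 genes. Genes were placed in classes on 2 WT replicates and the WT change was taken from the replicate left out. In log2 units the gap instead widened. Among raised genes, mean changes were 0.313 in WT and 0.112 in pent1 in the lowest class, and 4.47 and 3.45 in the highest. Among lowered genes they were -0.318 and -0.07, and -3.43 and -2.43. Choosing genes by WT alone favours a ratio below 1, and its effect within each class was not measured.

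Genes that ABA raised in WT were higher in pent1 mock than in WT mock. Chance values of the shared WT mock libraries predict no such excess for genes chosen as raised by ABA within pent1, yet their median log2 difference under mock was 0.17, and 0.08 to 0.21 with 1 library left out, lowest without pent1 ABA replicate 3 (0.08) and pent1 mock replicate 2 (0.11). Genes that ABA lowered in pent1 had a median of 0.11 under mock (0.18 and 0.19 without pent1 mock replicates 1 and 3), which a choice on the same pent1 mock libraries pushes upward. A difference between the tables stays open, since 24.9% of genes without an ABA call in WT also differed under mock and genotype cannot be told apart from table. A partly active ABA response in pent1 without added hormone may be another candidate explanation, and these data do not separate it from plants of a different state at the start. The values for it go both ways. Genes that ABA lowered in WT were lower in pent1 mock (median -0.24), and genes raised in both genotypes were higher (0.23, 684 higher and 184 lower). Genes lowered in both had a median of 0.002 (210 higher, 198 lower). Their choice partly on pent1 mock pushes this median upward. The 37 genes near silence in WT mock and on in WT ABA stood in pent1 mock at a median of 1.61% of their pent1 ABA level.

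By fitted values, 216 genes were at least 16-fold lower in pent1 mock and 15 at least 16-fold higher. Of the 216, 162 were also at least 16-fold lower under ABA and 25 had no count in any pent1 library. Too few reads is argued against by the depth, since the smallest pent1 mock library held 1.04 times the counts of the largest WT mock library. Loss of runs of neighbouring genes had its forecast met, with 4 pairs next to each other in the order of IDs against a mean of 1.35 in 10000 random draws (one-sided permutation p = 0.0479), but the 133 genes at least 16-fold higher with ABA in WT, which nothing removed, also had an excess (3 against 0.502, p = 0.0141), and 208 of the 216 genes had no neighbour in the set, which argues against runs as the source of most of the set. Lost runs may thus account for at most a few of these genes, while sequence differences from the reference and a difference between the tables stay open and were not tested.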
